A study of Mus musculus with 10 samples.

How the data were processed

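Total RNA was extracted with TRIzol and polyadenylated RNA was made into dUTP stranded libraries with 8 PCR cycles, sequenced as 51 bp single reads, per the labels' protocols. The cells labelled cardiomyocytes received DMSO at no more than 0.05%, with 5 nM TCDD in the TCDD groups. The deposited table holds whole-number counts per gene for 10 samples, which the authors had not normalized. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat and edgeR and the genome build mm10. The counting tool, its strand setting and the annotation release are not given in the sources used here.

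The table holds 24541 rows, all but 1 named by a gene symbol. The unnamed row held 0.000201 to 0.00285% of a library's counts and was left out of library sizes and tests. Entrez identifiers in the table matched RefSeq GRCm38 (the assembly of mm10) for 24472 genes, with the same symbol for 23880 and a gene span within 1000 bp for 24107. Printed coordinates are the RefSeq GRCm38 spans matched by Entrez identifier, 1-based. Columns were assigned to samples by name, and groups come from the labels: ES cells, DMSO 24 h, and TCDD 24, 72 and 96 h, with 2 libraries each. Depth was 15326612 to 31192459 counts per library.

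Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test on all 10 libraries, with 1 mean per group, TMM factors, the default expression filter and robust dispersion, which left 15175 genes (61.8%) and 5 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided, within each of 7 comparisons. CPM were computed from TMM-scaled library sizes and log2 CPM used a prior count of 2. Errors are SD of CPM over 2 libraries or SE of the fitted log2 fold change. A gene with 0 counts in a group was set at 3 counts over the group. One with more, up to a mean of 3 counts per library, has a ratio with an exact 95% Poisson interval for its own count. Replicate pairs were compared by chi-square over genes with at least 50 counts.

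Lists of genes, 32 in number, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members entered camera (limma 3.58.1) with a preset correlation of 0.01, adjusted over the lists of a comparison, and camera with an estimated correlation and fry were alternatives. In comparisons against DMSO or ES cells the rule named 17 fixed genes, the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 CPM and no overlap between libraries, without predicted or small RNA genes, and up to 4 members of each list by smallest p. Between TCDD times it named the 5 largest each way and the list members. Where 5 or fewer genes passed, all were named. Some genes that the rule names are not reported here.

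Alternatives chosen at the same time were other scaling factors (RLE, upper quartile), no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, other sets of libraries in the fit, the replicate number as a block, a stricter threshold, a minimum fold and each library left out in turn. Added after seeing the data were an offset for the GC trend of each library (loess of span 0.3, with GC content for 98.87% of tested genes), its combinations with the block, with the cardiomyocyte libraries alone and with an estimated correlation, the removal of structural RNA genes, and the joint removal of ES replicate 2, TCDD 24 h replicate 1 and TCDD 72 h replicate 1. Where a removal left a group with 1 library, that library was assumed to vary like the other groups. Relations between comparisons sharing libraries were set beside 50 simulated draws of unchanged groups and, as a check added after seeing the data, computed with 1 DMSO library per comparison.

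The edgeR script was tested on simulated counts modelled on TCDD 96 h versus DMSO (15043 genes tested), with 100 genes changed 2-fold and 100 changed 4-fold. With the pooled dispersion it recovered 12% and 92% of them, with 8 false calls, and with the dispersion between the DMSO libraries 100% and 100%, with 9. With the measured GC trends added it recovered 46% and 92%. In a test of camera, a planted list of 15 members reached an adjusted p of 1.77e-27 (0.00238 with an estimated correlation) and 0 of 32 others was called. Its genes were drawn independently and without GC trends. It therefore does not show how often camera calls unchanged lists whose members move together.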

Results

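Polyadenylated RNA was sequenced from 10 libraries of mouse cells in 5 groups of 2. One group held untreated embryonic stem (ES) cells of a C57BL/6N line whose construct joins the promoter of the cardiac factor Nkx2.5 to puromycin resistance and GFP. The other groups held cells differentiated from that line with Noggin, BMP4 and puromycin and labelled cardiomyocytes. They had received DMSO alone for 24 h, or 5 nM TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a ligand of the aryl hydrocarbon receptor, AHR) for 24, 72 or 96 h. The design asks how expression differed between ES cells and control cardiomyocytes and how it moved with the length of exposure. DNA methylation, which it also names, was not analysed here.

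Totals per library ran from 15326612 counts (TCDD 72 h replicate 1) to 31192459 (DMSO replicate 1). Between 17145 and 18392 genes had a count in each library. The limit that a count of 0 allows, 3 counts per library, lay between 0.0962 and 0.196 CPM, the count scaled to library size. This limit used library totals without TMM factors, unlike the other CPM values, so it is approximate on their scale. Intervals and limits of this kind cover counting error only, since the reads carried no molecular identifiers. The intervals given with ratios below cover the error of the ES count alone and take the DMSO level as fixed. They are therefore too narrow where DMSO counts are also small. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Every pair of replicates differed by more than sampling noise, but unequally. The chi-square statistic per gene was 3.228 for DMSO, 18.94 at 96 h, 86.5 at 24 h, 191.5 at 72 h and 196.5 for ES cells. ES replicate 2 and TCDD 24 h replicate 1 stood apart by GC content, with a range of 2.35 and 1.55 log2 units across transcripts ordered by GC. TCDD 72 h replicate 1 stood apart in RNA classes: the ribosomal RNA gene Rn45s took 10.95% of its counts, against 1.447 to 4.221% in the other libraries. Nuclear transcripts were high in the same library, where Malat1 reached 2776 CPM against 418.2 in its partner and Neat1 259.2 against 31.99.

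**Figure D1:**
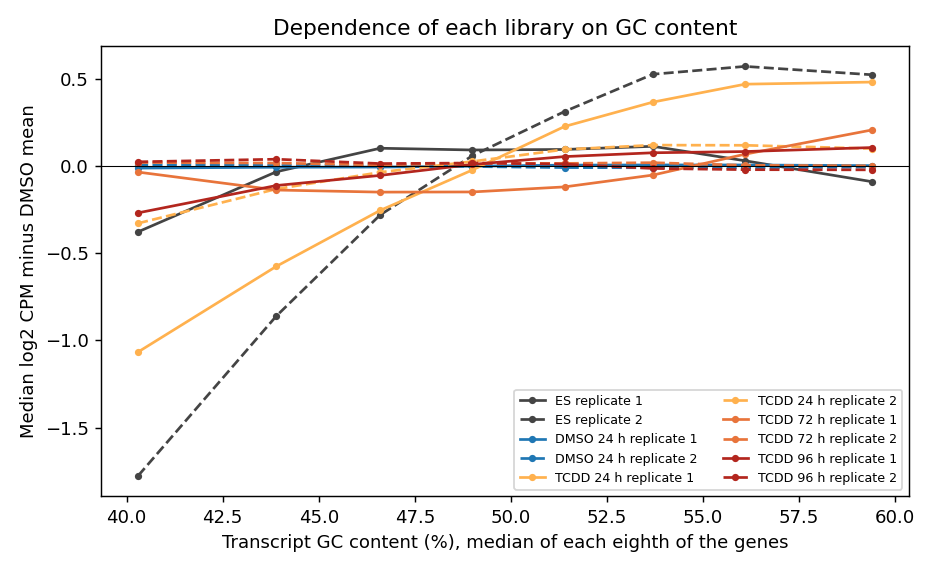
Median log2 CPM of each library minus the mean of the DMSO libraries (vertical axis) against transcript GC content in percent (horizontal axis), with the genes in 8 bins and 1 line per library. ES replicate 2 spans 2.35 log2 units and TCDD 24 h replicate 1 spans 1.55, while both DMSO libraries span 0.02. The DMSO libraries are set against their own mean, so a GC trend common to both cannot show.

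The libraries labelled cardiomyocytes kept high levels of pluripotency transcripts and low levels of heart muscle transcripts. Pou5f1, which encodes the pluripotency factor Oct4 (Entrez 18999, GRCm38 chromosome 17, 35506032 to 35510777), stood at 1012 ± 38.6 CPM in DMSO cells (SD, n = 2). ES cells had 1680 ± 577 (SD, n = 2), from 1272 and 2089 CPM. In the 6 TCDD libraries it ranged from 805.6 to 1516 CPM. Nkx2-5, the gene whose promoter drove selection (Entrez 18091, chromosome 17, 26838664 to 26844988), ran from 0.3987 to 3.656 CPM over all 10 libraries. Of 25 sarcomere genes, 10 had a mean under 1 CPM and 3 a mean over 10 CPM in DMSO cells. Of 23 cardiac transcription factors, 10 were under 1 CPM and 4 over 10 CPM. Mean log2 CPM in DMSO cells was 1.48 ± 0.006 over sarcomere genes and 7.28 ± 0.004 over pluripotency genes (SD, n = 2). Markers of other lineages were also measured in DMSO and ES cells, where mean log2 CPM was 5.06 against 2.69 for epithelial genes and 3.44 against 0.81 for smooth muscle genes. It was 2.37 against 1.79 for neural genes, 2.18 against 2.58 for endothelial genes, 0.73 against 1.23 for endoderm genes and −0.25 against −0.71 for blood and macrophage genes.

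**Figure D2:**
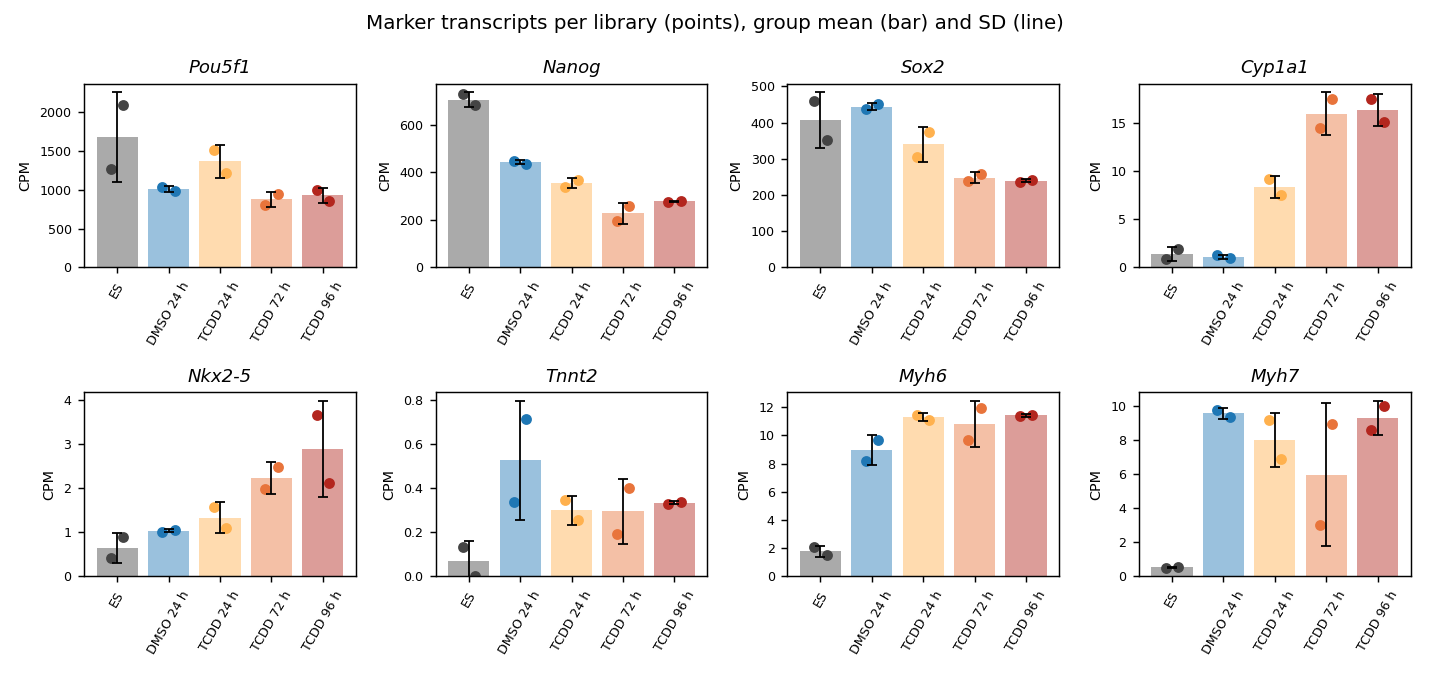
CPM of 8 transcripts per library, with bars for the group mean and lines for the SD (n = 2); each panel has its own axis from 0. Pou5f1 lies between 805.6 and 2089 CPM in all 10 libraries, whereas Nkx2-5 stays at or under 3.656 CPM.

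**Figure D3:**
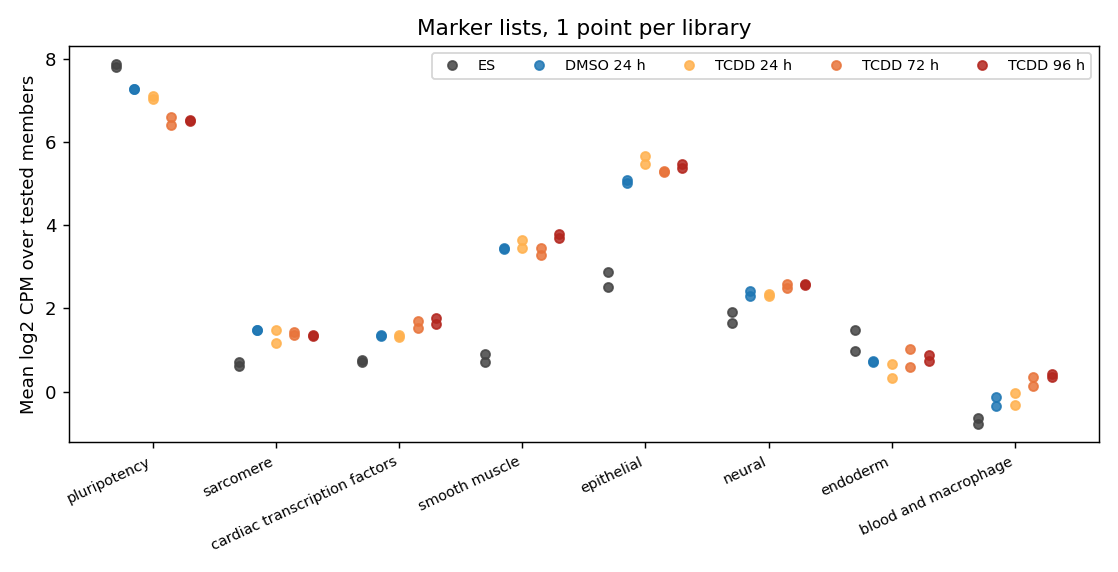
Mean log2 CPM over the tested members of 8 marker lists, 1 point per library, by group. Pluripotency genes averaged 7.84 in ES cells, 7.28 in DMSO cells and 6.53 at 96 h of TCDD, against 0.67, 1.48 and 1.35 for sarcomere genes.

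In DMSO cardiomyocytes versus ES cells, the smooth muscle actin gene Acta2 rose from 1.69 ± 0.316 to 283.8 ± 2.05 CPM (SD, n = 2, 168-fold, log2 fold change 7.39 ± 0.47 SE, adjusted p = 2.62e-05). Enpp2, which encodes the secreted enzyme autotaxin, rose to 37.8 ± 2.49 CPM (SD, n = 2, edgeR adjusted p = 6.29e-06). It had 4 counts over both ES libraries, for a ratio of 403 with a 95% counting interval of 157 to 1480. Grb10, an imprinted adaptor of growth factor receptors, fell by 4.95 on the log2 scale, from 282 ± 27.3 to 9.11 ± 0.0913 CPM (SD, n = 2). In all, 2349 genes rose and 2348 fell among 15175 tested. With the GC trend removed edgeR called 6186 (2956 higher and 3230 lower), of which 4373 were among the 4697 called without the offset. DESeq2 called 5009 genes and limma-voom 4896. Without the 3 libraries that stood apart it was 8027, and with only the 4 libraries compared in the fit 2337. The count was 1902 without DMSO replicate 2, 1954 without DMSO replicate 1 and 7736 without ES replicate 1. At least 2-fold change and the same threshold were met by 2068 rises and 1566 falls.

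Several of the largest rises in DMSO cells started from almost no ES counts. Has2, the hyaluronan synthase gene, had 296 counts in DMSO cells and 0 in ES cells, which makes it at least 79.1-fold higher against 3 counts over the ES group. Fgf5, a growth factor of the epiblast, had 1244 counts against 1, a ratio of 997 with a 95% counting interval of 179 to 39400. The ratios were 478 for Vrtn (132 to 3950), 405 for Wisp1 (72.6 to 16000), 269 for Fndc3c1 (92.2 to 1310) and 217 for Kctd12b (60 to 1790). Actg2, Bmp2 and Wnt5a had 4, 6 and 6 ES counts and ratios of 36.1 (14.1 to 132), 25.1 (11.5 to 68.4) and 16.7 (7.67 to 45.5). Beside Grb10, the largest falls were in the citrate transporter gene Slc13a5 (log2 −5.65), Slc51a (−5.15), B3gnt3 (−5.10), Vax2 (−5.01), Cyp2b23 (−4.64), Hal (−4.62) and Catsperz (−4.60). Cyp2b23 belongs to a family of similar genes, and Acta1, Acta2, Actc1 and Actg2 encode nearly identical actins, so reads may be split among such copies. Pou5f1, Nanog, Dppa3, Krt18 and Ldha have processed copies elsewhere in the genome and carry the same uncertainty. Whether counting used strand is not given in the sources used here, so genes with an antisense partner are uncertain too.

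The pluripotency list divided in DMSO cardiomyocytes versus ES cells. Of 25 tested members, 10 fell and 3 rose (11 and 3 adjusted over the list alone), with a median log2 change of −0.52. Camera ranked the list lower (adjusted p = 0.000309, adjusted p = 0.0713 with an estimated correlation). Tbx3 fell from 222 to 19.9 CPM (log2 −3.48), Klf5 from 166 to 24.3 CPM (−2.77), Klf4 from 232 to 43.2 CPM (−2.42) and Nanog from 704.8 ± 30.4 to 441 ± 8.35 CPM (SD, n = 2, −0.68, adjusted p = 0.0274). Pou5f1 did not pass (−0.73 ± 0.27 SE, adjusted p = 0.0635). Dppa3, a germline and naive-state gene, rose against the list from 5.25 ± 0.846 to 105 ± 5.53 CPM (SD, n = 2, 4.32).

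Some cardiac genes rose from a low base in the same comparison, while the sarcomere and cardiac transcription factor lists did not pass camera. The cardiac stress and calcium handling lists did pass with the preset correlation and are given below. Myh6 and Myh7, the cardiac myosin heavy chain genes, rose from 1.75 ± 0.402 to 8.94 ± 1.07 CPM (2.34 ± 0.25 SE, adjusted p = 0.000262) and from 0.513 ± 0.0363 to 9.55 ± 0.326 CPM (4.21 ± 0.52 SE, adjusted p = 0.000526; SD, n = 2). Tnnt2, the cardiac troponin T gene, had 26 counts against 3 (ratio 6.94, 2.38 to 33.7, adjusted p = 0.0386), and Nppa, the atrial peptide gene, had 32 against 4 (ratio 6.41, 2.5 to 23.5, adjusted p = 0.0159). The Tnnt2 call ended without ES replicate 2, DMSO replicate 1 or DMSO replicate 2 (adjusted p = 0.169, 0.0721 and 0.22). The Nppa call ended without ES replicate 2 or DMSO replicate 1 (0.0633 and 0.148). Nkx2-5 did not pass (1.03 ± 0.0303 against 0.64 ± 0.341 CPM, SD, n = 2, 0.69, adjusted p = 0.275). Of 21 sarcomere genes 8 rose and 1 fell (9 and 1 adjusted over the list alone), and camera did not pass (adjusted p = 0.0757, adjusted p = 0.359 with an estimated correlation). Tpm1 rose from 73.9 ± 6.21 to 508 ± 7.85 CPM (SD, n = 2, 2.78), while Mypn fell (−4.48). Of 20 cardiac transcription factors 6 rose and 2 fell (7 and 2 adjusted over the list alone), including Hand1 (2.50), Irx4 (3.88) and Prdm16 (−2.00), with a camera adjusted p of 0.213 (adjusted p = 0.348 with an estimated correlation).

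Camera ranked 11 of the 32 lists higher and 4 lower in DMSO cardiomyocytes versus ES cells. None of the 15 calls held with an estimated correlation, where the lowest adjusted p was 0.0608. Smooth muscle genes rose in 9 of 12 members, with none lower (9 adjusted over the list alone, camera adjusted p = 4.61e-09, adjusted p = 0.0608 with an estimated correlation), led by Tagln (3.91 ± 1.33 to 271 ± 7.82 CPM, SD, n = 2), Cnn1 (5.53) and Actg2 (5.06). Epithelial genes rose in 10 of 13 (10 adjusted over the list alone, 9.47e-10, adjusted p = 0.0608 with an estimated correlation), with the keratins Krt8 (17.2 ± 5.59 to 472 ± 5.08 CPM, SD, n = 2) and Krt18 (4.95) and the regulators Esrp1 (3.80) and Grhl2 (3.81). Of 11 epicardial and mesothelial genes 7 rose and 1 fell (7 and 1 adjusted over the list alone, 0.000659, adjusted p = 0.0908 with an estimated correlation), with Wt1 at 4.86 and Msln at −2.35. Of 21 fibroblast and matrix genes 11 rose and 5 fell (11 and 5 adjusted over the list alone, 0.00286, adjusted p = 0.348 with an estimated correlation), with Col3a1 at 4.33 and Col5a2 at −2.94. Of 8 skeletal muscle genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, 0.0287, adjusted p = 0.348 with an estimated correlation), with Tnnt3 at 3.27 and Mylpf at −0.99. Without ES replicate 1 the fibroblast and skeletal muscle calls ended (adjusted p = 0.0882 and 0.363).

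Signalling, imprinted and stress genes followed in DMSO cardiomyocytes versus ES cells. Wnt pathway genes rose in 18 of 35 members and fell in 3 (19 and 3 adjusted over the list alone, camera adjusted p = 5.35e-06, adjusted p = 0.185 with an estimated correlation), including Lef1 (5.24), Wnt5a (4.03) and the antagonist Sfrp1 (−2.05). BMP and TGF-beta genes rose in 11 of 28 and fell in 2 (12 and 2 adjusted over the list alone, 4.99e-05, adjusted p = 0.0673 with an estimated correlation), including Tgfb2 (4.78), Bmp2 (4.63), Nog (3.96) and Smad1 (−1.54). Imprinted genes rose in 14 of 27 and fell in 1 (18 and 2 adjusted over the list alone, 1.09e-05, adjusted p = 0.0608 with an estimated correlation): Igf2 went from 13.4 ± 0.238 to 301 ± 7.59 CPM (SD, n = 2). Cardiac stress genes rose in 6 of 8 (6 adjusted over the list alone, 3.66e-05, adjusted p = 0.0673 with an estimated correlation), led by Acta1 (5.85) and Cryab (2.52). Calcium handling genes rose in 7 of 18 and fell in 1 (7 and 1 adjusted over the list alone, 0.0132, adjusted p = 0.348 with an estimated correlation), with Jph2 at 3.19. Immediate early genes rose in 8 of 16 and fell in 2 (8 and 2 adjusted over the list alone, 0.0104, adjusted p = 0.386 with an estimated correlation), with Egr1 at 2.81 and Ier2 at −1.01. The calcium handling and immediate early calls ended without ES replicate 1 (adjusted p = 0.0523 and 0.244).

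Camera ranked fatty acid oxidation, oxidative phosphorylation and unfolded protein genes lower in DMSO cardiomyocytes versus ES cells. Fatty acid oxidation genes fell in 10 of 22, with none higher (12 adjusted over the list alone, camera adjusted p = 0.000309, adjusted p = 0.348 with an estimated correlation). Cpt1a, which encodes the carnitine palmitoyltransferase of mitochondrial fatty acid import, fell from 178 to 15.8 CPM (−3.50) and Fabp3 by 1.88. Oxidative phosphorylation genes fell in 8 of 25 and rose in 1 (8 and 1 adjusted over the list alone, 0.00778, adjusted p = 0.56 with an estimated correlation), with Cox5a at −1.51. Cycs, the cytochrome c gene, was the member that rose (0.94, adjusted p = 0.0371), but its estimate was −0.082 once the GC trend was removed. Unfolded protein and amino acid response genes fell in 8 of 16 and rose in 2 (9 and 2 adjusted over the list alone, 0.000327, adjusted p = 0.348 with an estimated correlation), with Chac1 at −3.20, Ddit3 at −2.40 and Hspa5 at 0.84. The de novo DNA methyltransferase genes Dnmt3a (157 ± 6.22 to 521 ± 10.5 CPM; 1.73, adjusted p = 0.00107) and Dnmt3b (208 ± 25.3 to 671 ± 17.5 CPM; 1.69, adjusted p = 0.00051) rose, and the maintenance gene Dnmt1 fell from 596 ± 42.9 to 334 ± 13.3 CPM (SD, n = 2, −0.83, adjusted p = 0.00947). Tet1 did not pass (0.33, adjusted p = 0.672), nor did the DNA methylation list of 20 genes (5 higher, 3 lower; 5 and 3 adjusted over the list alone; camera adjusted p = 0.292). Of the AHR genes, Ahr (2.66, adjusted p = 0.0037) and Cyp1b1 (3.42 ± 0.32 SE, adjusted p = 0.000125) rose and Nqo1 fell (−1.31, adjusted p = 0.0249), while Cyp1a1 (−0.29), Ahrr (−0.21) and Tiparp (0.60) did not pass. Without ES replicate 1 Tiparp did (1.89, adjusted p = 0.000729). The calls of Nqo1, Nanog, Dnmt1, Fabp3, Cycs, Mylpf, Hspa5 and Ier2 ended without either DMSO library (adjusted p = 0.0582 to 0.189).

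TCDD 24 h versus DMSO is the comparison at a matched time, and no gene passed the edgeR test on all libraries. Cyp1a1, the cytochrome P450 gene that AHR ligands induce, had the largest separation among the AHR genes, at 8.32 ± 1.16 CPM against 1.10 ± 0.21 in DMSO cells (SD, n = 2, log2 fold change 2.89 ± 0.36 SE, adjusted p = 0.247). Nqo1 stood at 63.9 ± 2.84 against 39.1 ± 0.851 CPM (SD, n = 2, 0.71, adjusted p = 0.521), Cyp1b1 at 5.42 against 5.77 CPM (−0.09), Ahrr at −0.54, Tiparp at 0.09 and Ahr at −0.52. Of 7 AHR target genes 4 were higher, 1 of them past the threshold adjusted over the list alone (camera adjusted p = 0.0632). With edgeR, 1296 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.247, while DESeq2 called 14 genes higher and 27 lower and limma-voom 0. Without the 3 libraries that stood apart edgeR called 418 genes higher and 348 lower, and with the GC trend removed 5 in all. TCDD 24 h replicate 1 carried the GC trend given above.

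Camera ranked 4 lists higher and 2 lower at 24 h, and none held with an estimated correlation (lowest adjusted p = 0.453). Here and at the later times, a list given without a count adjusted over the list alone had 0 members past that threshold. In TCDD 24 h versus DMSO, glycolysis genes were higher in 20 of 22 members (0 adjusted over the list alone, median log2 0.54; camera adjusted p = 6.36e-06, adjusted p = 0.555 with an estimated correlation), with the lactate dehydrogenase gene Ldha at 1891 ± 345 against 1075 ± 53.6 CPM and the lactate transporter gene Slc16a3 at 281 ± 72.3 against 120 ± 4.5 CPM (SD, n = 2). Oxidant response genes of the NRF2 list were higher in 16 of 17 (0.00269, adjusted p = 0.555 with an estimated correlation), with the metallothionein gene Mt2 at 511 ± 56.5 against 329 ± 15.7 CPM (SD, n = 2). Epithelial genes were higher in 11 of 13 (0.000737, adjusted p = 0.453 with an estimated correlation), with the tight junction gene Cldn7 at 62.4 ± 13.6 against 31.3 ± 1.41 CPM (SD, n = 2). Oxidative phosphorylation genes were higher in 19 of 25 (0.0376, adjusted p = 0.916 with an estimated correlation). BMP and TGF-beta genes were lower in 20 of 28, 3 of them adjusted over the list alone (0.00101, adjusted p = 0.453 with an estimated correlation), with Bmp2 at 1.14 ± 0.0851 against 3.59 ± 0.535 CPM (SD, n = 2). Hox genes, which pattern the body axis, were lower in 18 of 24 (0.00282, adjusted p = 0.511 with an estimated correlation). The oxidative phosphorylation call ended without TCDD 24 h replicate 1 (adjusted p = 0.0782) or DMSO replicate 2 (0.0762), and the Hox call without TCDD 24 h replicate 2 (0.0814).

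Identity genes did not pass singly at 24 h of TCDD. Pou5f1 stood at 1367 ± 211 against 1012 ± 38.6 CPM (SD, n = 2, 0.43, adjusted p = 0.521), Nanog at −0.32, and Klf4 at 20.8 ± 1.67 against 43.2 ± 4.09 CPM (SD, n = 2, −1.05, adjusted p = 0.374). Of 25 pluripotency genes 18 were lower, 1 of them adjusted over the list alone (median −0.22, camera adjusted p = 0.0832). Dnmt3b was at 1328 ± 153 against 671 ± 17.5 CPM (SD, n = 2, 0.99 ± 0.21 SE, adjusted p = 0.391), Dnmt3a at 0.36, Dnmt1 at 0.10 and Tet1 at −0.91. The heart genes Nkx2-5 (0.37), Myh6 (0.34), Myh7 (−0.25), Tnnt2 (−0.75) and Nppa (−0.13) did not pass either. The sign for Nppa changed without DMSO replicate 1 (0.45) or TCDD 24 h replicate 2 (0.11).

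TCDD 72 h versus DMSO set cells exposed for 72 h beside a control labelled 24 h, so exposure and time in culture differ together, as they do at 96 h. Cyp1a1 (Entrez 13076, chromosome 9, 57687928 to 57703824) rose 14.2-fold, to 16.0 ± 2.19 from 1.10 ± 0.21 CPM (SD, n = 2, 3.83 ± 0.37 SE, edgeR adjusted p = 0.0134), and was the gene that rose. The 6 genes that fell included 3 regulators of the naive pluripotent state. Klf4 (16600, chromosome 4, 55527137 to 55532475) fell 4.82-fold to 8.96 ± 1.33 from 43.2 ± 4.09 CPM (SD, n = 2, −2.27 ± 0.22 SE, adjusted p = 0.0134). Nr0b1 (11614, chromosome X, 86191775 to 86195947) fell to 7.30 ± 1.53 from 27.1 ± 1.71 CPM (SD, n = 2, −1.89, adjusted p = 0.0285) and Prdm14 (383491, chromosome 1, 13113428 to 13127163) to 3.03 ± 0.161 from 11.2 ± 0.144 CPM (SD, n = 2, −1.89, adjusted p = 0.0176). Inhbb, which encodes an activin subunit (16324, chromosome 1, 119415463 to 119422248), fell to 0.833 ± 0.0122 from 9.97 ± 0.0944 CPM (SD, n = 2, −3.57 ± 0.34 SE, adjusted p = 0.0134). The chromodomain gene Cdyl2 (75796, chromosome 8, 116568723 to 116732991) fell by 2.16 on the log2 scale (adjusted p = 0.0288). The kinase gene Aurkc (20871, chromosome 7, 6995347 to 7003091), which lies outside the size rule and was chosen after its values were seen, fell by 3.23 (adjusted p = 0.0176).

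The count at 72 h depended on single libraries, on the libraries in the fit and on the tool. Without TCDD 72 h replicate 2 it was 969 (759 higher and 210 lower), and it was 0 without TCDD 72 h replicate 1, DMSO replicate 1 or DMSO replicate 2. Without the 3 libraries that stood apart it was 1967 (950 and 1017), with the GC trend removed 473 (199 and 274), with the 8 cardiomyocyte libraries alone 288 (155 and 133) and with only the 4 libraries compared 0. DESeq2 called 310 genes (172 and 138) and limma-voom 5 (1 and 4), and 2215 had an unadjusted p under 0.05. The balance of 1 higher and 6 lower was thus not kept in the larger sets.

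Pluripotency genes formed the list with the clearest shift in TCDD 72 h versus DMSO. Of 25 members 21 were lower, 3 past the threshold over all genes and 15 adjusted over the list alone, with a median of −0.79 (camera adjusted p = 1.31e-17, adjusted p = 0.00727 with an estimated correlation). This was the call that held with an estimated correlation. Esrrb stood at 99.5 ± 18 against 242 CPM (SD, n = 2, −1.29, adjusted p = 0.103), Nanog at 226 ± 42.8 against 441 CPM (−0.96, adjusted p = 0.107) and Pou5f1 at 876 ± 99 against 1012 CPM (SD, n = 2, −0.21, adjusted p = 0.794). AHR target genes ranked higher, with 1 of 7 past the threshold (2 higher and 1 lower adjusted over the list alone; median 0.86; 0.00116, adjusted p = 0.101 with an estimated correlation). Cyp1b1 was at 13.7 ± 1.84 against 5.77 CPM (SD, n = 2, 1.24, adjusted p = 0.107), Ahrr at 0.89, Tiparp at 0.63 and Ahr at 0.42. Nqo1 was at 70.8 ± 44 against 39.1 ± 0.851 CPM (SD, n = 2, 0.86, adjusted p = 0.313), with 39.7 CPM in replicate 1 and 102 in replicate 2. Its change was 1.38 without replicate 1 and −0.002 without replicate 2. All 16 targets of p53 were higher, 5 of them adjusted over the list alone (0.00132, adjusted p = 0.101 with an estimated correlation), with the cell cycle inhibitor gene Cdkn1a at 195 ± 12.9 against 104 ± 0.478 CPM (SD, n = 2, 0.91, adjusted p = 0.177). Both the AHR and the p53 calls ended without TCDD 72 h replicate 2 (adjusted p = 0.266 for each).

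Other lists passed camera in TCDD 72 h versus DMSO and were lost with an estimated correlation. Imprinted genes were higher in 22 of 27, 6 adjusted over the list alone (0.0047, adjusted p = 0.195 with an estimated correlation). Meg3 was at 294 ± 305 against 51 ± 4.08 CPM (SD, n = 2), from 509.5 CPM in the library with high nuclear transcripts and 78.39 in its partner. Immediate early genes were higher in 12 of 16 (1 adjusted over the list alone, 0.0109, adjusted p = 0.619 with an estimated correlation), calcium handling genes in 15 of 18 (0.015, adjusted p = 0.619 with an estimated correlation) and Wnt genes in 28 of 35 (2 adjusted over the list alone, 0.0158, adjusted p = 0.619 with an estimated correlation), while cell cycle genes were lower in 20 of 28 (0.0152, adjusted p = 0.638 with an estimated correlation). Without TCDD 72 h replicate 1 the calcium handling, cell cycle and Wnt calls ended (adjusted p = 0.373, 0.373 and 0.378), as they did without all 3 libraries that stood apart (0.552, 0.249 and 0.285). The immediate early, calcium handling and Wnt calls ended without DMSO replicate 1 (0.0647, 0.14 and 0.111), and the immediate early call also without TCDD 72 h replicate 2 (0.146) and with the GC trend removed (0.062). Cardiac transcription factors (14 of 20 higher, camera adjusted p = 0.3) and sarcomere genes (13 of 21 lower, 0.506) did not pass. Nkx2-5 was at 2.22 ± 0.364 against 1.03 ± 0.0303 CPM (SD, n = 2, 1.12, adjusted p = 0.267), Myh6 at 0.28, Tnnt2 at −0.72 and Nppa at 0.85. Myh7 was at 5.94 ± 4.19 against 9.55 ± 0.326 CPM (SD, n = 2, −0.67, adjusted p = 0.513). It was at 2.98 CPM in replicate 1, whose ribosomal and nuclear RNA were high, and 8.91 in replicate 2. Its change was −0.10 without replicate 1 and −1.703 without replicate 2 (adjusted p = 0.0275). Dnmt1 (−0.37), Dnmt3a (−0.46), Dnmt3b (0.38) and Tet1 (0.08) did not pass.

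In TCDD 96 h versus DMSO, 6 genes rose and 7 fell. Cyp1a1 rose 14.5-fold to 16.3 ± 1.67 CPM (SD, n = 2, 3.86 ± 0.37 SE, edgeR adjusted p = 0.0124). The matrix gene Efemp1 (Entrez 216616, chromosome 11, 28853154 to 28926743) rose to 9.46 ± 0.521 from 1.93 ± 0.0314 CPM (SD, n = 2, 2.29, adjusted p = 0.0232). The lipoxygenase gene Alox15 (11687, chromosome 11, 70344147 to 70390538) rose by 2.23 (adjusted p = 0.0333), the neurofilament gene Nefm (18040, chromosome 14, 68119545 to 68125004) by 2.01 (adjusted p = 0.0246) and the reelin adaptor gene Dab1 (13131, chromosome 4, 103619500 to 104744844) by 1.58 (adjusted p = 0.0447). Lor, the loricrin gene (16939, chromosome 3, 92080271 to 92083142), chosen after its values were seen, rose by 3.19 (adjusted p = 0.0246).

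The falls at 96 h of TCDD again held Klf4 (8.22 ± 0.405 CPM, SD, n = 2, −2.39 ± 0.22 SE, adjusted p = 0.0124), Prdm14 (2.59 ± 0.152 CPM, SD, n = 2, −2.11, adjusted p = 0.0124) and Nr0b1 (−1.73, adjusted p = 0.0323). Inhbb (−3.05, adjusted p = 0.0156), Cdyl2 (−2.12, adjusted p = 0.0262) and Aurkc (−2.45, adjusted p = 0.0323; also outside the size rule) fell too, with Mymx, a myoblast fusion gene (653016, chromosome 17, 45600961 to 45602196), at −2.04 (adjusted p = 0.0447). The count was 0 without any 1 of the 4 libraries compared, TCDD 96 h replicate 1, TCDD 96 h replicate 2, DMSO replicate 1 or DMSO replicate 2. Without the 3 libraries that stood apart it was 4397, with the GC trend removed 621 (297 higher and 324 lower), with the 8 cardiomyocyte libraries alone 380 (194 and 186) and with only the 4 libraries compared 4383. DESeq2 called 249 genes (109 and 140) and limma-voom 19 (7 and 12), and 1850 had an unadjusted p under 0.05.

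**Figure D4:**
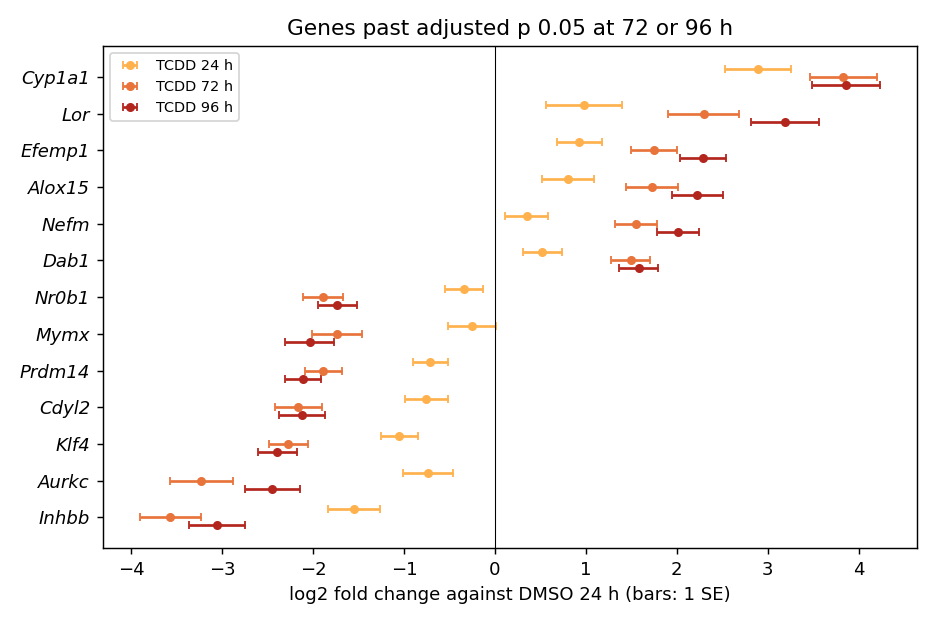
Log2 fold change against the DMSO 24 h group, with bars of 1 SE, for the 13 genes past an adjusted p of 0.05 at 72 or 96 h, shown at 24, 72 and 96 h of TCDD. Cyp1a1 lies at 2.89, 3.83 and 3.86, and Klf4 at −1.05, −2.27 and −2.39.

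Pluripotency genes were lower in 23 of 25 members in TCDD 96 h versus DMSO, 3 past the threshold over all genes, with 14 lower and 1 higher adjusted over the list alone (median −0.68; camera adjusted p = 2.69e-18, adjusted p = 0.011 with an estimated correlation). It was the call at this time that held with an estimated correlation. Esrrb was at 103 ± 3.07 against 242 CPM (SD, n = 2, −1.24, adjusted p = 0.0814), Nanog at −0.67 and Pou5f1 at −0.13. AHR target genes ranked higher, with 1 of 7 past the threshold and 3 adjusted over the list alone (median 0.71; 4.67e-05, adjusted p = 0.0565 with an estimated correlation). Cyp1b1 was at 12.9 ± 0.848 CPM (SD, n = 2, 1.16, adjusted p = 0.103), Nqo1 at 83.8 ± 4.05 CPM (SD, n = 2, 1.10, adjusted p = 0.24), Ahrr at 0.59, Tiparp at 0.71 and Ahr at 0.38. Immediate early genes were higher in 13 of 16 (7 adjusted over the list alone, 3.26e-06, adjusted p = 0.357 with an estimated correlation), with the stress factor gene Atf3 at 15.8 ± 0.914 against 5.97 CPM (SD, n = 2). Targets of p53 were higher in 15 of 16 (5 adjusted over the list alone, 9.06e-05, adjusted p = 0.0565 with an estimated correlation), with Btg2 at 110 ± 2.79 against 57.5 CPM and Phlda3 at 144 ± 14.6 against 63.4 CPM (SD, n = 2).

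Patterning and cardiac lists also passed camera in TCDD 96 h versus DMSO. Wnt genes were higher in 28 of 35 (3 adjusted over the list alone, 0.0018, adjusted p = 0.435 with an estimated correlation), with Wnt6 at 16.5 ± 1.24 against 4.18 CPM (SD, n = 2). Hox genes were higher in 18 of 24 (0.0193, adjusted p = 0.449 with an estimated correlation), NRF2 genes in 14 of 17 (0.0333, adjusted p = 0.509 with an estimated correlation), epithelial genes in 9 of 13 (0.0459, adjusted p = 0.449 with an estimated correlation) and cardiac transcription factors in 15 of 20 (0.0475, adjusted p = 0.343 with an estimated correlation). All 4 of these calls ended without TCDD 96 h replicate 1 (adjusted p = 0.054, 0.134, 0.134 and 0.181), and the NRF2, epithelial and cardiac factor calls without DMSO replicate 1 (0.0728, 0.0924 and 0.083). Removing the GC trend ended the Hox, epithelial and cardiac factor calls (0.0596, 0.0596 and 0.0626), and the 3 libraries left out together ended the Hox and cardiac factor calls (0.112 and 0.134). Nkx2-5 was at 2.88 ± 1.09 against 1.03 ± 0.0303 CPM (SD, n = 2, 1.49, adjusted p = 0.169), Myh6 at 0.36, Myh7 at −0.04, Tnnt2 at −0.60 and Nppa at −0.01. Sarcomere genes were lower in 13 of 21 (1 adjusted over the list alone, camera adjusted p = 0.579), with the cardiac actin gene Actc1 at 9.91 ± 1.77 against 2.59 CPM (SD, n = 2, 1.93, adjusted p = 0.177). Dnmt1 (−0.22), Dnmt3a (−0.41), Dnmt3b (0.42) and Tet1 (−0.80) did not pass, nor did the DNA methylation list (1 lower adjusted over the list alone, camera adjusted p = 0.24).

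Setting the exposure times against each other avoids the DMSO group, but exposure and time in culture still differ together. Comparisons with TCDD 24 h rest on 2 libraries whose deviation from the DMSO mean correlated with GC content at 0.675 and 0.372. In TCDD 72 h versus TCDD 24 h, pluripotency genes were lower in 24 of 25 (9 adjusted over the list alone, median −0.49; camera adjusted p = 2.12e-08, adjusted p = 0.0477 with an estimated correlation), with Nr0b1 at 7.30 ± 1.53 against 21.3 ± 1.34 CPM (SD, n = 2, −1.54), Prdm14 at −1.18, Klf4 at −1.22 and Esrrb at −1.24. Glycolysis genes were lower in 21 of 22 (9 adjusted over the list alone, 2.12e-08, adjusted p = 0.51 with an estimated correlation), with the phosphofructokinase gene Pfkp at 42.2 ± 3.56 against 86.1 ± 7.31 CPM (SD, n = 2, −1.03). Hox genes were higher in 22 of 24 (3 adjusted over the list alone, 0.000111, adjusted p = 0.388 with an estimated correlation). Imprinted genes were higher in 19 of 27 (9 adjusted over the list alone, 0.00706, adjusted p = 0.374 with an estimated correlation). Oxidative phosphorylation (20 of 25 lower; 0.00261, adjusted p = 0.574 with an estimated correlation), fatty acid oxidation (18 of 22 lower; 0.00554, adjusted p = 0.537 with an estimated correlation) and cell cycle genes (21 of 28 lower; 0.00624, adjusted p = 0.537 with an estimated correlation) passed camera, as did Wnt (28 of 35 higher; 0.0188, adjusted p = 0.537 with an estimated correlation) and p53 genes (15 of 16 higher; 0.0266, adjusted p = 0.374 with an estimated correlation). Without TCDD 72 h replicate 1 the fatty acid oxidation, oxidative phosphorylation, Wnt and cell cycle calls ended (adjusted p = 0.274, 0.554, 0.274 and 0.101), the first 3 also without all 3 libraries that stood apart (0.117, 0.571 and 0.225). The Wnt and p53 calls ended without TCDD 24 h replicate 2 (0.132 for each), and the p53 call without TCDD 72 h replicate 2 (0.509). No single gene passed with edgeR (3285 with an unadjusted p under 0.05, smallest adjusted p = 0.149; 489 higher and 133 lower by DESeq2, 0 by limma-voom), but 1442 did without TCDD 72 h replicate 2 (1052 and 390), 924 without the 3 libraries that stood apart (316 and 608) and 1240 with the 8 cardiomyocyte libraries alone (841 and 399).

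TCDD 96 h versus TCDD 24 h gave the same directions for pluripotency, Hox and glycolysis genes, against the same TCDD 24 h libraries. In those libraries glycolysis genes had ranked higher and Hox genes lower than in DMSO cells. Pluripotency genes were lower in 23 of 25 (6 adjusted over the list alone, median −0.52; camera adjusted p = 1.02e-10, adjusted p = 0.0383 with an estimated correlation), with Prdm14 at −1.41 and Klf4 at −1.34. Hox genes were higher in 22 of 24 (5 adjusted over the list alone, 8.46e-09, adjusted p = 0.164 with an estimated correlation). Glycolysis genes were lower in 20 of 22 (2 adjusted over the list alone, 1.69e-05, adjusted p = 0.478 with an estimated correlation), with Pfkp at −0.94 and Pdk1 at −0.99. Wnt genes were higher in 27 of 35 (3 adjusted over the list alone, 0.000508, adjusted p = 0.338 with an estimated correlation), p53 targets in 13 of 16 (1 adjusted over the list alone, 0.00253, adjusted p = 0.164 with an estimated correlation), BMP and TGF-beta genes in 21 of 28 (3 adjusted over the list alone, 0.00487, adjusted p = 0.317 with an estimated correlation) and immediate early genes in 12 of 16 (0.0243, adjusted p = 0.541 with an estimated correlation). Imprinted genes were higher in 20 of 27 (4 adjusted over the list alone, 0.0458, adjusted p = 0.317 with an estimated correlation) and AHR targets in 5 of 7 (2 adjusted over the list alone, 0.0476, adjusted p = 0.317 with an estimated correlation), with Cyp1a1 at 0.97 and Cyp1b1 at 1.25. Endothelial genes were lower in 8 of 14 (4 adjusted over the list alone, 0.0458, adjusted p = 0.541 with an estimated correlation), with Robo4 at −1.76. Without TCDD 24 h replicate 2 the AHR, imprinted and immediate early calls ended (adjusted p = 0.218, 0.158 and 0.377). The AHR and endothelial calls ended without TCDD 96 h replicate 1 (0.141 and 0.0682) and with the GC trend removed (0.0941 and 0.202), and the imprinted call without TCDD 96 h replicate 2 (0.0972). No single gene passed with edgeR (1761 with an unadjusted p under 0.05, smallest adjusted p = 0.157; 129 by DESeq2, 0 by limma-voom), but 1828 did without the 3 libraries that stood apart and 83 with the 8 cardiomyocyte libraries alone.

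In TCDD 96 h versus TCDD 72 h camera ranked 6 lists higher at 96 h, and none held with an estimated correlation (lowest adjusted p = 0.567). Smooth muscle genes were higher in 8 of 12 (1 adjusted over the list alone, camera adjusted p = 0.000914, adjusted p = 0.567 with an estimated correlation), with Tagln at 532 ± 20.6 against 312 ± 27.6 CPM and Cnn1 at 70.7 ± 8.05 against 32.8 ± 10.3 CPM (SD, n = 2). Acta1, of the cardiac stress list (5 of 8 higher, 1 adjusted over the list alone, 0.0417, adjusted p = 0.704 with an estimated correlation), was at 88.9 ± 7.35 against 40.0 ± 1.73 CPM (SD, n = 2, 1.15). Oxidative phosphorylation (23 of 25 higher; 0.000914), glycolysis (18 of 22; 0.00596), fatty acid oxidation (18 of 22; 0.0287) and cell cycle genes (21 of 28; 0.0417) also passed camera, each with adjusted p = 0.704 with an estimated correlation. Without TCDD 72 h replicate 1, whose ribosomal and nuclear RNA were high, the calls of all of these but smooth muscle ended (adjusted p = 0.939, 0.0835, 0.66, 0.833 and, for cardiac stress, 0.52), with oxidative phosphorylation and fatty acid oxidation then on the lower side. The glycolysis, fatty acid oxidation, cell cycle and cardiac stress calls ended without TCDD 96 h replicate 1 (0.111, 0.111, 0.091 and 0.225). The last 3 ended without TCDD 96 h replicate 2 (0.0572, 0.0572 and 0.385), and cardiac stress without TCDD 72 h replicate 2 (0.406). No gene passed with edgeR (710 with an unadjusted p under 0.05, smallest adjusted p = 0.935; 0 by DESeq2 and limma-voom), but 331 did without TCDD 72 h replicate 2.

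Fold changes were set against each other across the 15175 genes, which are not independent replicates. The 72 h and 96 h changes against DMSO correlated at r = 0.649, where unchanged groups sharing those controls gave 0.485 (covariance 0.219 against 0.0979, or 0.0291 simulated with the spread of the DMSO libraries). The overlap was 1 gene higher and 6 lower in both. Unchanged groups sharing those controls gave 0 and 0 in 50 draws. Those draws made a mean of 0.14 calls at 72 h and 0.18 at 96 h, too few to set a no-change value for overlap. Independent lists, which leave the shared controls out, gave 0.000395 and 0.00277. Between 24 and 96 h r was 0.48 (simulated 0.505), with a covariance of 0.147 against 0.0985, or 0.0287 with the spread of the DMSO libraries. Between 24 and 72 h r was 0.185 (simulated 0.483, or 0.449 with the spread of the DMSO libraries). The covariance of 0.0668 for 24 and 72 h lay under the simulated 0.0982 but over the 0.029 simulated with the DMSO spread. By covariance, the reading of that pair depends on the spread assumed. Each set of draws gave all groups the same spread, whereas the DMSO pair varied least (chi-square per gene 3.228). The simulated r, and covariances from the pooled spread, can therefore overstate in size what sharing these controls gives, here and below. The check with 1 DMSO library per comparison, given below, does not rest on an assumed spread. The change from ES cells to DMSO cells correlated with that from DMSO to TCDD at −0.23 for 24 h, 0.171 for 72 h and 0.133 for 96 h. Unchanged groups gave −0.49, −0.474 and −0.495. The covariances were −0.185, 0.152 and 0.1 against −0.0981, −0.0984 and −0.0986. Simulated with the spread of the DMSO libraries, those covariances were −0.0288, −0.0294 and −0.0288. At 96 h, 3 genes were higher in both (0.929 by independent lists) and 7 lower in both (1.08), and at 72 h 6 were lower in both (0.928). The draws of unchanged groups gave 0 for each of these, again with too few calls to set a no-change value for overlap. Neither value holds both the effects and the shared controls, so part of an excess may come from those controls. With 1 DMSO library for each of the comparisons set side by side, an added check over the same 15175 genes, r was 0.514 for 72 and 96 h, 0.348 for 24 and 96 h and 0.113 for 24 and 72 h (covariance 0.2, 0.122 and 0.0461). With the ES to DMSO change it was −0.189 for 24 h, 0.174 for 72 h and 0.147 for 96 h. The ES to DMSO change shares no library with the changes from 24 to 72 h and from 24 to 96 h of TCDD. Here r was 0.311 and 0.359, where simulated values were −0.00112 and −0.00223. Covariances were 0.337 and 0.285 against −0.000234 and −0.000454. The draws held no GC trend. Deviation from the DMSO mean correlated with GC content at 0.0544 and 0.46 in the ES libraries and 0.675 and 0.372 in the TCDD 24 h libraries. These values thus cannot tell a shared GC trend from a link between the changes.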

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

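The GC offset, its use with an estimated correlation and the test of time in culture were chosen only after the data were seen, while the reading of the GC and replicate tests was set before their results.

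Pluripotency genes were lower at 72 and 96 h than at 24 h of TCDD by the test of the difference itself, and were not called between 72 and 96 h. The list median was −0.492 in TCDD 72 h versus TCDD 24 h and −0.524 in TCDD 96 h versus TCDD 24 h, against −0.053 in TCDD 96 h versus TCDD 72 h (14 of 25 lower, camera adjusted p = 0.67, with the mean at 0.002 and the test on the higher side). Both calls held with an estimated correlation (adjusted p = 0.0477 and 0.0383), but not once the GC trend was also removed (adjusted p = 0.0793 and 0.0511), although the medians were then −0.493 and −0.562. GC bias does not account for the fall against DMSO at 96 h, since the median with the GC offset was −0.687 against −0.68 without it. The 96 h libraries departed little from DMSO by GC (ranges of 0.38 and 0.06 log2 units), so the offset had little to remove. This test does not bear on the comparisons with TCDD 24 h. RNA quality in TCDD 72 h replicate 1 does not account for the fall against DMSO at 72 h, since the median without that library was −0.685 against −0.79. Time in culture cannot be told apart from TCDD at 72 and 96 h, because the DMSO group is labelled 24 h: the matched 24 h median was −0.223, with an interquartile range of 0.43.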

How the results depend on the processing

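The GC offsets and the removal of 3 libraries together (ES replicate 2, TCDD 24 h replicate 1, TCDD 72 h replicate 1) and the split of the DMSO controls were chosen only after the results were seen. Unless stated, the cause of a change was not tested. RLE and upper-quartile factors, the CPM filter and the removal of structural RNA kept each count of genes within 1.5 times its value, though RLE gave 7 higher and 9 lower at 96 h. Depth limits low genes, since 3 counts were worth 0.0962 to 0.196 CPM by library totals without TMM factors.

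Counts of genes, by setting: without the 3 libraries they were 8027 (DMSO cardiomyocytes versus ES cells), 766 (24 h versus DMSO), 1967 (72 h), 4397 (96 h), 924 (72 h versus 24 h), 1828 (96 h versus 24 h) and 2 (96 h versus 72 h). DESeq2 gave 41, 310 and 249 at 24, 72 and 96 h, and 622 and 129 for 72 and 96 h versus 24 h. The GC offset gave 5, 473 and 621, then 4 and 80, and with the cardiomyocyte libraries alone 5, 806 and 1053, then 1907 and 292. Cardiomyocyte libraries alone, without the offset, gave 1, 288 and 380, then 1240 and 83. No filter gave 1, 59 and 98, then 9 and 2. With only the groups compared the counts were 2337 (DMSO versus ES), 0 (72 h), 4383 (96 h) and 1430 (72 h versus 24 h), with fewer samples behind the spread. An adjusted p under 0.01 left 2287, 0 and 0 for DMSO versus ES, 72 h and 96 h. All 7 genes at 72 h and all 13 at 96 h were shared with the calls of DESeq2 and of the GC offset. Where a removal leaves a group with 1 library (ES, 24 h and 72 h without the 3), that lone library is assumed to vary like the other groups. Leaving out 1 library gave 1902 to 7736 for DMSO versus ES, 0 to 969 at 72 h, 0 to 0 at 96 h, 0 to 1442 for 72 h versus 24 h and 0 to 331 for 96 h versus 72 h.

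Replicate numbers were not shown to pair the libraries: same-numbered deviations correlated from −0.755 (ES and 24 h) to 0.448 (24 and 96 h). With the number as a block the counts were 3728 for DMSO versus ES, 0 at 72 h and 0 at 96 h, and with the GC offset and the block 145 at 72 h, 291 at 96 h and 3 for 96 h versus 24 h. Cycs, 0.94 in DMSO versus ES, was −0.082 with the GC offset and −0.052 with the offset and block.

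List calls with an estimated correlation were 0 for DMSO versus ES, 0 at 24 h, 1 at 72 h, 1 at 96 h, 1 for 72 h versus 24 h, 1 for 96 h versus 24 h and 0 for 96 h versus 72 h. With the GC offset as well they were 3, 0, 1, 1, 0, 0 and 0. Fry, which tests whether a list's genes move one way, gave 24 for DMSO versus ES, 0 at 24 h, 3 at 72 h, 6 at 96 h, 7 for 72 h versus 24 h, 7 for 96 h versus 24 h and 0 for 96 h versus 72 h. Without the 3 libraries camera called 10 lists at 24 h and 12 for 96 h versus 72 h. Without 1 library it called 5 (DMSO replicate 1) to 9 (DMSO replicate 2) at 72 h, 5 (96 h replicate 1) to 10 (96 h replicate 2) at 96 h, and 3 (96 h replicate 1) to 7 (72 h replicate 1) for 96 h versus 72 h.

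Over genes with a mean of at least 5 CPM, the ES to DMSO change correlated at −0.353 with 24 h, 0.239 with 72 h, 0.105 with 96 h, 0.459 with 72 h versus 24 h and 0.462 with 96 h versus 24 h. Changes against DMSO correlated at 0.152 (24 and 72 h), 0.467 (24 and 96 h) and 0.666 (72 and 96 h). With 1 DMSO library per comparison, over 15869 genes without the CPM limit, these 3 were 0.0554, 0.266 and 0.414, and those of the ES to DMSO change with 24, 72 and 96 h −0.163, 0.151 and 0.135. Over the 15175 genes also tested with the control shared, the split gave 0.113, 0.348 and 0.514 against 0.185, 0.48 and 0.649, and −0.189, 0.174 and 0.147 against −0.23, 0.171 and 0.133, so part of the drop came from the genes included. The split also leaves a noisier control behind each change. Named genes were counted once per comparison, most of them without a call. With DESeq2 363 stayed on their side of the threshold and 53 gained a call. With the GC offset 378 stayed, 41 gained a call, 1 lost it, 1 reversed and 3 changed sign without a call in either fit. With limma-voom 426 stayed and 2 lost their call.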

Other observations

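All tests in this part were chosen only after the results were seen. Genes of the naive and formative pluripotent states differed in direction in DMSO cardiomyocytes versus ES cells. The formative list was higher in 10 of 11 members, with Fgf15 at 5.98 against 0.722 CPM, Sox3 at 11.1 against 0.873 and the cadherin gene Cdh2 at 9.34 against 0.825. Values of 4 members had been seen before the list was written, and Krt18 is in the epithelial list. Over the other 6, 5 were higher, 3 rose and 1 fell, with a median log2 change of 1.934 (camera p = 0.00284), which did not pass with an estimated correlation (p = 0.0871). The rule first used left out 4 members and kept Krt18, for a median of 3.041 over 7 (p = 0.0122 with an estimated correlation), so the result rests on that choice. The naive list had a median of −0.91, with Esrrb at 242 against 1030 CPM, Tfcp2l1 at 98.7 against 392 and Tcl1 at 25.1 against 79. Of its members 9 are in the pluripotency list already described, so its fall is not independent evidence, and 4 formative members are in other lists. Etv4 (−1.62) and Dppa3 (4.32) went against their lists.

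In TCDD cells the naive list lay below DMSO, with a median of −0.289 at 24 h (adjusted p = 0.0506 with an estimated correlation), −1.28 at 72 h (0.00077) and −0.993 at 96 h (0.00119), where time in culture differs as well. Between exposure times its median was −0.61 for 72 h versus 24 h and −0.63 for 96 h versus 24 h (0.00721 and 0.00729). The naive list shares 9 members with the pluripotency list already tested in these comparisons, so its fall is not independent evidence. Its adjusted p-values cover the naive and formative lists alone. They cannot be compared with those adjusted over the fixed lists. Over the 6 formative members the median against DMSO was 0.2 at 24 h, 0.471 at 72 h and 0.31 at 96 h (camera p = 0.119, 0.0308 and 0.0995, and p = 0.299, 0.172 and 0.275 with an estimated correlation), and between times 0.169 for 72 h versus 24 h, 0.023 for 96 h versus 24 h and −0.136 for 96 h versus 72 h (0.676, 0.951 and 0.562). Esrrb stood at 99.5 CPM at 72 h and 103 at 96 h, Tfcp2l1 at 46.5 and 43.1, and Tcl1 at 10.1 and 10.9.

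Libraries labelled cardiomyocytes had high Pou5f1 and low cardiac transcripts. Pou5f1 stood at 63.3 to 119% of the lower ES library in all 8. An exchange of ES and cardiomyocyte libraries is argued against by genes other than these: 0 of the 8 had a mean log2 CPM over smooth muscle genes nearer to the ES libraries (at most 0.91) than to the other cardiomyocyte libraries, at 3.29 to 3.8. Cultures made mostly of unchanged ES cells are argued against too: of 3443 genes at 50 CPM or more in ES cells, 29 lay under 0.25 times their lower ES level in all 8 libraries, among them Sohlh2 (155 ± 21.3 CPM in ES cells, SD, n = 2, at most 7.61 in the others) and Cobl (196, at most 9.98). A move of cells from naive to formative pluripotency stays open, since the formative median of 1.934 over 6 members passed camera with the preset correlation alone. Cell sorting or single-cell data, not analysed here, would be needed to tell this from a mixture of states.

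Replicates of ES cells and of TCDD 24 h differed along 1 axis. GC bias between libraries is a candidate explanation: across genes, the ES replicate difference correlated with GC content at −0.711, and removing the trend lowered its SD from 0.855 to 0.578, or by 32.3%. At 24 h r was 0.728 and the drop 33.6%. Transcript length stays open, with a correlation of 0.281 after the GC trend was removed. No biological explanation was tested, since the labels give none between replicates.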
